A study of Mus musculus with 5 samples.

How the data were processed

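Haematopoietic stem cells (HSCs) from mouse bone marrow were profiled by Smart-seq2, a method that amplifies full-length cDNA from few cells and keeps neither strand nor molecule identifiers. Per the labels' protocols, 30 cells were sorted into lysis buffer for each library by surface markers (negative for lineage markers and CD34, positive for Sca-1, c-kit and CD150) and sequenced as paired 150-bp reads. The table deposited by the authors holds raw read counts per gene symbol for 5 libraries, with 35976 gene rows and no rows of unassigned reads. HISAT2 2.2.1, HTSeq 0.12.4 and the build mm10 are listed in the submitters' processing notes. The gene annotation, the strand setting and the treatment of reads that match several places are not given in the sources used here. Symbols were matched to a RefSeq gene table of the mouse assembly GRCm38.p6, which is mm10, and 32501 of the 35976 symbols (90.3%) matched. Coordinates come from that table and are 1-based.

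Groups follow the sample labels, which give 2 WT and 3 Ythdf3-/- libraries, each of a C57BL/6 mouse. The series text instead counts 2 knockout and 3 wild-type samples. It says that the 5 samples came from different mice, so replicates are animals. Because the counts of Ythdf3 itself go against the labels, libraries are named throughout as labelled WT or labelled Ythdf3-/-. Any direction given as lower or higher in one group refers to those labels alone.

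Counts were tested in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16. Genes were kept by its default filter on expression per group, scaled by TMM factors and fitted robustly with no covariate, and the p-values were adjusted by the Benjamini-Hochberg method at 0.05. Standard errors of log2 fold changes were derived from the F statistic. CPM values, the usual depth-scaled counts, were computed from the deposited counts of each library divided by its total. A gene's groups were said not to overlap when every library of one label lay above every library of the other, which chance gives for 20% of genes. In all, 30 lists were fixed before the data were examined, holding 752 genes of which 747 were rows of the table; they cover stem cell and cell cycle programmes, translation, metabolism, stress and signalling, the markers of other cell types that the sort could hold, and nuclear RNA. Lists with at least 5 tested genes were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), adjusted over the 26 lists, and again with an estimated correlation. Fry was run beside them. The 4 library measures were compared by an exact permutation test, two-sided, for which 2 libraries against 3 give 10 arrangements and a smallest p of 0.2.

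The genes named were set by a rule fixed before the data were examined. Ythdf3, Ythdf1, Ythdf2 and Ccnd1 were named whatever their result. Because no gene passed in either direction, 8 per direction with the smallest unadjusted p followed, among genes with given names, a mean of at least 10 CPM and groups that do not overlap. For each list the 2 tested members with the smallest p were added. Of the 75 genes so named, 74 had a span in the RefSeq table, and 33 of those spans overlap another annotated gene. Without strand, reads that lie in exons of more than 1 gene cannot be assigned. The spans include introns, and overlap of exons was not examined. Genes with near-identical copies, here the globin genes and the ribosomal protein genes with processed pseudogenes such as Rpl41 and Rps29, are uncertain as well. For these the reason is that the treatment of reads matching several places is not given. Genes named outside the rule are said to be so, and some genes that the rule names are not reported here.

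Totals ran from 6357862 to 16650134 counts per library, so 1 count was worth between 0.0601 and 0.157 CPM. Shares of counts in a library are given with 95% Wilson intervals; these cover counting error alone, since reads amplified without molecule identifiers are not independent molecules. The test was tried on simulated counts with the real means, library sizes and fitted spread. It called 4 of 100 genes changed 4-fold and 26 of 100 genes changed 16-fold among 10593 genes tested, with 4 false calls. With the dispersion set to 0.1 it called 91 and 100 of 100 among 11091 genes, with 8 false calls. The changed genes were always drawn from genes above a minimum mean CPM, so these rates do not cover genes of lower level. In the simulation with the fitted spread, camera from limma separated a list shifted as a whole from an unchanged one. The simulated genes were drawn independently, so this does not show how camera behaves where members of a list vary together. In the real data the estimated correlation was 0.693 for ribosomal proteins and 0.287 for oxidative phosphorylation. It was 0.227 for DNA replication and 0.156 for mitosis, against the preset 0.01.

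Alternatives fixed before the data were examined were 3 other scalings, no filter, a stricter filter (10 CPM in 2 libraries), the fit without robust estimation, DESeq2 1.42.0, limma voom with sample weights, the replicate number as a block, each library left out, thresholds of 0.1 or of 2-fold, a prior count of 0.5, and detection at 10 counts or after thinning to the smallest total. A fit without the libraries labelled WT 2 and Ythdf3-/- 1 was added after seeing the data. Intervals and figures were made in Python 3.11.15 with SciPy 1.17.1 and matplotlib 3.10.9. Splicing, RNA methylation and protein were not analysed here.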

Results

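The transcriptomes of HSCs carrying labels of 2 genotypes were measured in 5 libraries of 30 cells each, 2 labelled WT and 3 labelled Ythdf3-/-. YTHDF3 is a cytoplasmic reader of N6-methyladenosine in mRNA, and the comparison asks which RNAs differ in abundance in stem cells that lack it. Total counts were 16650134 and 8968162 in the libraries labelled WT 1 and WT 2, and 6357862, 9076806 and 7016670 in those labelled Ythdf3-/- 1, 2 and 3. At least 1 count was present for 13151 and 12431 genes in the libraries labelled WT and for 11109, 11830 and 11759 genes in those labelled Ythdf3-/-.

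The targeted gene was read first, as a check of the labels, and it went against them. Ythdf3 (chromosome 3, 16183148 to 16217037 in mm10) had 20 and 29 counts in the libraries labelled WT 1 and WT 2. It had 339 and 366 counts in the libraries labelled Ythdf3-/- 2 and 3, and 2 counts in the library labelled Ythdf3-/- 1. The mean was 2.22 ± 1.44 CPM (SD, n = 2) under the WT label and 29.9 ± 26.7 CPM (SD, n = 3) under the Ythdf3-/- label. The difference did not pass either test (log2 fold change 3.64, SE 2.65, edgeR adjusted p = 0.9998; exact permutation test, two-sided, p = 0.6). The labels do not describe the allele, and gene-level counts cannot show whether the reads of the libraries labelled Ythdf3-/- come from an intact transcript.

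The other readers of the same family were present in all 5 libraries. Ythdf1 (chromosome 2, 180904377 to 180920936) stood at 40.9 ± 33.6 CPM (SD, n = 2) under the WT label and 50.3 ± 15.1 CPM (SD, n = 3) under the Ythdf3-/- label. Ythdf2 (chromosome 4, 132184916 to 132212256) stood at 217 ± 45.7 CPM and 155.6 ± 57.4 CPM. Ccnd1 (chromosome 7, 144929931 to 144939831), the cyclin D1 gene of the G1 phase, had 196 and 562 counts under the WT label and 90, 21 and 1 under the Ythdf3-/- label. Its log2 fold change was -2.86 with an SE of 2.27, and became -1.14 without the library labelled WT 2 and -4.97 without that labelled Ythdf3-/- 1. That of Ythdf2, -0.58, became -0.28 without the library labelled WT 2 and -0.27 without that labelled Ythdf3-/- 1. None of these 3 genes passed the edgeR test (adjusted p = 0.9998 for each).

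**Figure D1:**
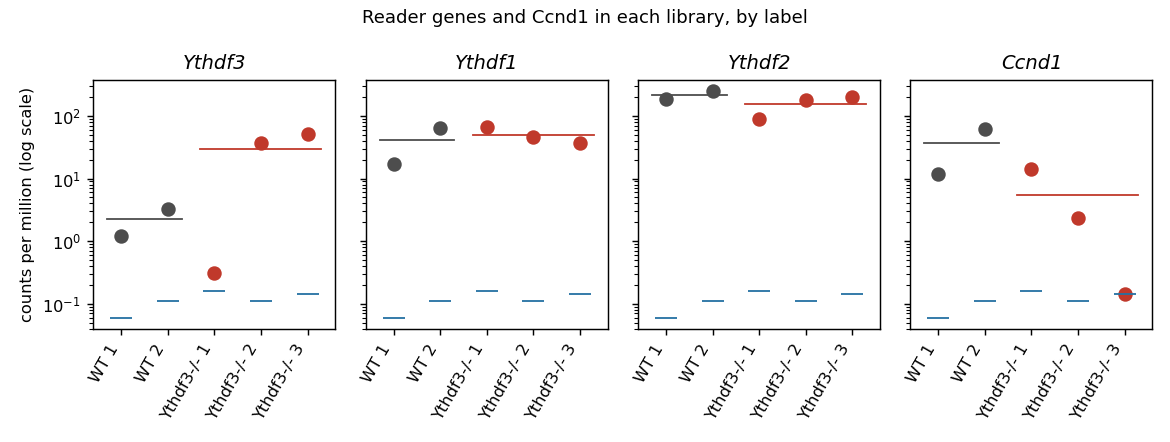
CPM (log axis) of Ythdf3, Ythdf1, Ythdf2 and Ccnd1 in each library, in grey for the WT label and red for the Ythdf3-/- label, with horizontal lines at the group means and blue dashes at the value of 1 count. Ythdf3 lies at 37.3 and 52.2 CPM in the libraries labelled Ythdf3-/- 2 and 3 and at 3.23 CPM or lower in the other 3.

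Across the transcriptome 0 genes passed the edgeR test between the labels and 0 passed limma voom, while 594 passed DESeq2 and 541 had an unadjusted p under 0.05 in edgeR. The genes closest to it were read in abundance under one label and nearly missing under the other. Dok2, an adaptor that restrains receptor tyrosine kinase signalling, had 585, 1451 and 902 counts in the libraries labelled Ythdf3-/- and 12 and 8 in those labelled WT. Atg4b, a protease of autophagy, had 1697, 762 and 548 against 20 and 14. Bcl2l1, which encodes the survival factor BCL-XL, had 1375, 446 and 672 against 36 and 26. Mpzl1, Tnip1 and Zfp961 had the same form, with means of 170.1, 99.7 and 99.8 CPM under the Ythdf3-/- label and of 2.46, 1.32 and 1.77 CPM under the WT label. Fam53a had 751, 1315 and 891 counts against 43 and 56. Tbc1d10c was present in all libraries and differed by a log2 fold change of 2.06 (SE 0.38), from 127.1 to 565.4 CPM.

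In the other direction, Skiv2l, a helicase of cytoplasmic RNA decay, had 2131 and 1351 counts under the WT label and 1, 3 and 4 under the Ythdf3-/- label. Ryk, a Wnt receptor, had 1964 and 813 against 4, 3 and 1. Itprip and Kif22, the latter a mitotic kinesin, had means of 79.9 and 89.0 CPM against 0.479 and 0.952 CPM. Lace1 and Rab40c had 1264 and 404, and 1181 and 433 counts, against 1 count in each library labelled Ythdf3-/-. Ccne1 (cyclin E1) and Ccnb2 (cyclin B2) rested mainly on the library labelled WT 2, where they had 2462 and 1653 counts. The library labelled WT 1 had 34 and 102 counts of them, and no library labelled Ythdf3-/- had more than 2.

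Among the 11146 genes tested these had the smallest p of those that met the naming rule, with adjusted p between 0.912 and 0.964 in edgeR; the span of Dok2 overlaps that of Xpo7 in the annotation. The 541 genes at an unadjusted p under 0.05 (235 higher and 306 lower under the Ythdf3-/- label) were 4.85% of those tested. The groups did not overlap for 2307 genes, 20.7% of those tested against 20% by chance. The genes called by DESeq2 were 398 higher and 196 lower and included 27 of the named genes. Counted after the calls were seen, 123 of the 398 and 10 of the 196 had counts in 1 library only, and 130 and 106 had at least 90% of their summed CPM in 1 library. EdgeR with no filter on low counts called 21, and edgeR without the library labelled WT 1 called 1, LOC101056014 (log2 fold change -1.82, adjusted p = 0.0164). That gene, chosen after its values were seen, made up 5.57% of counts in the library labelled WT 2 (95% interval 5.56 to 5.59) and between 1.49% and 1.82% elsewhere. Without the library labelled WT 1 the unadjusted count was 1016. Of the 21 genes called with no filter, the globin gene Hba-a1 had the smallest adjusted p (edgeR, 2.02e-53). That gene, named outside the rule, had 117770 counts in the library labelled Ythdf3-/- 1 and at most 2438 elsewhere. Others of the 21, such as Dok2 and Skiv2l, differed between the labels in every library. The common biological coefficient of variation was 1.26.

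**Figure D2:**
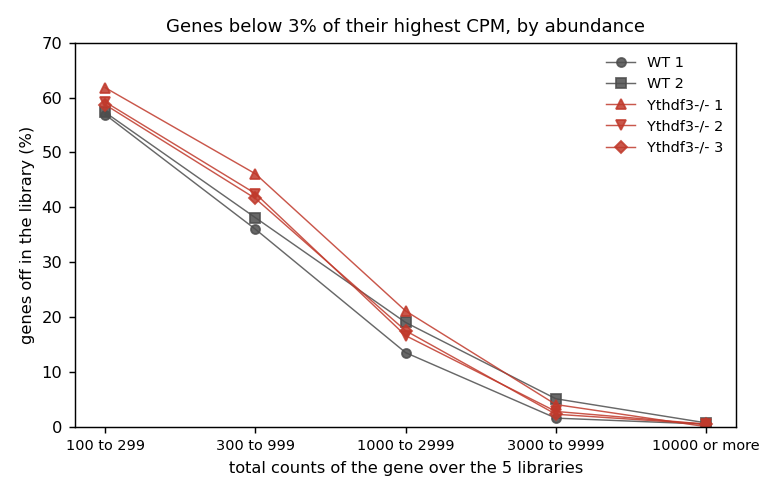
Percent of genes whose CPM in a library was below 3% of the gene's highest CPM among the 5 libraries (vertical axis), by the gene's total count over the libraries (horizontal axis), with 1 line per library. The share over all libraries goes from 58.8% at totals of 100 to 300 counts to 0.418% at 10000 counts or more.

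With camera, 4 of the 26 lists tested were lower under the Ythdf3-/- label, and none of the 4 with an estimated correlation, where the adjusted p = 0.917 for each. Fry, which tests a list's own genes and not against the others, called none of the 4 (adjusted p = 0.539 for ribosomal proteins, 0.386 for mitosis, 0.569 for oxidative phosphorylation and 0.593 for DNA replication). The direction was down under each of the 4 scalings. Messages of cytosolic ribosomal proteins fell as a group (adjusted p = 8.53e-05): 79 of 80 members had a lower fitted level, and 43 of 80 were lower in every library labelled Ythdf3-/-. Rpl41 averaged 1424 CPM under the WT label and 627 CPM under the Ythdf3-/- label, and Rps29 averaged 419 and 162.5 CPM; reads of both can be shared with processed pseudogenes. The log2 fold change of Rpl41, -1.28, became -0.81 without the library labelled WT 2. Nuclear-encoded genes of oxidative phosphorylation fell with them (adjusted p = 0.00922; 64 of 76 lower), among them Cox6b1 with 641 against 302 CPM and Uqcrq with 285.5 against 103.0 CPM. Mitosis genes fell (adjusted p = 0.000119; 19 of 23 lower), with Cdca8 at 95 and 871 counts against 0, 1 and 4. DNA replication genes fell (adjusted p = 0.0112; 21 of 30 lower), with Pold1 at 374 and 683 counts against 0, 1 and 1 and Tk1 at 57 and 1176 against 4, 2 and 5. No member of the 4 lists passed the edgeR test over all genes, and 0 passed adjusted over the list alone.

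Without the library labelled WT 2 the adjusted p was 0.486 for ribosomal proteins and for mitosis, 0.727 for oxidative phosphorylation and 0.717 for DNA replication. The lists' median log2 fold changes went from -0.70 to -0.24, from -1.31 to 0.28, from -0.59 to -0.072 and from -0.58 to -0.0065 in that order. Without the library labelled Ythdf3-/- 2 or Ythdf3-/- 3, DNA replication had adjusted p of 0.203 and 0.213 and medians of -0.30 and -0.35. Oxidative phosphorylation had adjusted p of 0.0541 and 0.123 with medians of -0.59 and -0.53, so there the p moved and the size hardly did. In contrast, without the library labelled WT 1 the median of HSC identity rose from 0.27 to 0.72 and that of the monocyte list from 0.40 to 4.72. That fit leaves 1 library labelled WT. With the stricter filter mitosis had an adjusted p of 0.107. Of 26 mitosis genes with at least 100 counts in all, 18 were highest in the library labelled WT 2, as were 14 of 30 replication genes. In that library genes of the erythroid lineage were high as well: Car1 had 4093 counts against at most 24 elsewhere, and Gata1, named outside the rule after its values were seen, had 1061 against at most 6. Ribosomal proteins took 12.1% of its counts (95% interval 12.1 to 12.1) and between 7.24% and 8.46% elsewhere. Without the libraries labelled WT 2 and Ythdf3-/- 1, a choice made after seeing the data that leaves 1 library labelled WT, mitosis (adjusted p = 0.0286) and DNA replication (0.0146) stayed below the threshold and the other 2 lists did not (0.459 and 0.612).

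**Figure D3:**
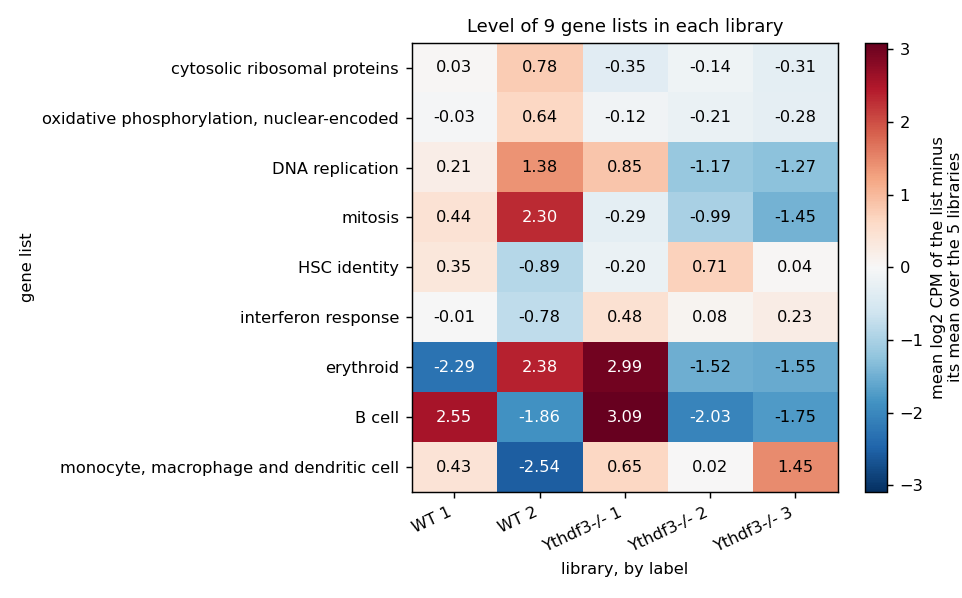
Mean log2 CPM of 9 gene lists in each library, less the list's mean over the 5 libraries (red above, blue below; the value is written in each cell). The 4 lists that passed camera, in the upper rows, are highest in the library labelled WT 2, by 2.30 for mitosis and 0.78 for ribosomal proteins.

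The programme of stem cell identity was read in every library and did not pass (30 members tested, adjusted p = 0.284, 19 fitted higher under the Ythdf3-/- label). Ly6a, which encodes Sca-1, averaged 110.1 and 273.9 CPM under the WT and Ythdf3-/- labels, and Clu had 46 and 3 counts against 1118, 129 and 591. Genes of G1 cyclins and the E2F axis went both ways (adjusted p = 0.311). Myc averaged 290.7 CPM under the WT label and 840.0 CPM under the Ythdf3-/- label (log2 fold change 1.45, SE 0.34). Adjusted over the list alone, 2 of its 15 tested members passed, Ccne1 and Myc, in opposite directions, against 0 over all genes tested. The quiescence list had an adjusted p of 0.311 with camera, and was the 1 list that passed fry's mixed test of change in either direction (adjusted p = 0.0171). The CDK inhibitor Cdkn2c had 319 and 142 counts against 1, 1 and 0, while the pocket protein gene Rbl1 had 2 and 99 against 471, 603 and 319. Among p53 targets and apoptosis genes (adjusted p = 0.397), 1 of 17 members passed adjusted over the list alone, Bcl2l1, and Bid averaged 30.4 and 168.9 CPM. The log2 fold change of Bid, 2.41, became 4.37 without the library labelled WT 1 and 1.63 without that labelled WT 2.

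Writers, readers and erasers of N6-methyladenosine were mostly lower under the Ythdf3-/- label without passing (15 of 21 lower, adjusted p = 0.311), but the list's median log2 fold change of -0.37 became 1.01e-05 without the library labelled WT 2. Ythdc1, the nuclear reader, averaged 183.1 and 73.4 CPM, but its log2 fold change of -1.42 became -0.36 without the library labelled WT 2. Averages of Zc3h13, a part of the writer complex, were 104.4 and 34.7 CPM. Translation factors (adjusted p = 0.75) included Eif5b at 218.9 and 81.4 CPM and Eif1ax at 146.0 and 41.4 CPM, whose log2 fold change of -1.93 became -0.99 without the library labelled WT 2. Interferon response genes had 30 of 37 members fitted higher (adjusted p = 0.212); Mx2 and Oasl1 were at 5 counts or fewer in the libraries labelled WT and Ythdf3-/- 3. Glycolysis genes (adjusted p = 0.54) included Eno1 at 539.3 and 1091 CPM and Aldoa at 1031 and 1628 CPM, with log2 fold changes of 0.94 and 0.58 that became 0.57 and 0.22 without the library labelled WT 2 and 1.47 and 1.10 without that labelled WT 1. Immediate early genes (0.92), the NF-kB response (0.92), chromatin regulators (0.92), antioxidant defence (0.92), the heat shock and unfolded protein response (0.949) and Wnt, Notch and TGF-beta signalling (0.336) did not pass. Their members with the smallest p were Klf6 (30.2 and 177.4 CPM) and Ier2, Traf1 and Rela, Kdm5a and Asxl2, Prdx1 and Sod1, Hspe1 (243.5 and 61.8 CPM) and Hspd1, and Notch2 (325.7 and 151.9 CPM) and Fzd7. For Hspe1 the log2 fold change of -2.09 became -0.90 without the library labelled WT 2. Mitochondrially encoded genes had an adjusted p of 0.338, with ND4 at 626.8 and 368.5 CPM and ND6 at 86.9 and 17.2 CPM, both highest in the library labelled WT 2. The median log2 fold change of that list, -0.835, became -1.45 without the library labelled WT 1 and 0.45 without that labelled WT 2. Each of those fits leaves 1 library labelled WT. The list's estimated correlation was 0.775, against the preset 0.01.

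Markers of other cell types were uneven among libraries of the same label, and none of their lists passed. The erythroid list (adjusted p = 0.92) was led by Car1 and by Hbb-bs, a beta globin gene with 51602 counts in the library labelled Ythdf3-/- 1 and at most 316 in the others. The 4 adult globin genes made up 3.55% of counts there (95% interval 3.54 to 3.57) and 0.0423% (0.041 to 0.0437) in the library labelled WT 2, the next highest. The median log2 fold change of the erythroid list went from 0.042 to -0.44 without the library labelled WT 1. It went to 5.53 without that labelled WT 2. The list's direction in camera, lower in the main fit, turned to higher without the library labelled WT 2, Ythdf3-/- 2 (adjusted p = 0.531) or Ythdf3-/- 3 (0.929). The list of monocyte, macrophage and dendritic cell genes had an adjusted p of 0.0505, higher under the Ythdf3-/- label. Without the library labelled WT 2 its direction turned to lower (adjusted p = 0.766, median log2 fold change from 0.40 to -0.23), and without that labelled Ythdf3-/- 3 the median was -0.44. The monocyte list passed camera as higher without the library labelled Ythdf3-/- 2 (adjusted p = 0.0197), and without that labelled WT 1 its median was 4.72. In this list C1qc had 364, 298 and 259 counts against 10 and 0, and C1qa 213, 1 and 164 against 8 and 0. The B cell list (0.92) included Vpreb1, with 3252 counts in the library labelled Ythdf3-/- 1 and at most 292 elsewhere. Without the library labelled WT 2 the median log2 fold change of the B cell list went from 0.59 to -1.04. The list's mean log2 CPM, less its mean over the libraries, was 2.55 and 3.09 in the libraries labelled WT 1 and Ythdf3-/- 1. It was -1.86, -2.03 and -1.75 in those labelled WT 2, Ythdf3-/- 2 and Ythdf3-/- 3. Estimated correlations were 0.779 for the B cell, 0.406 for the erythroid and 0.314 for the monocyte list, against the preset 0.01. Leaving out a library labelled WT leaves 1 under that label. The lists of multipotent progenitors (0.92; Notch1), megakaryocytes and platelets (0.849; Nrgn and Gp1ba), neutrophils and granules (0.892; Lyz2 and Csf3r) and sex-linked genes (0.672; Xist and Ddx3y) did not pass. T and NK cells (Nkg7 and Lck), stromal and endothelial cells (Emcn and Pecam1) and abundant nuclear RNA (Neat1 and Malat1) had fewer than 5 tested genes, and mast cells, basophils and eosinophils had 0. For 6 lists (erythroid, megakaryocyte, B cell, NF-kB, heat shock and chromatin regulators) the test, the median and the mean differed in sign.

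More genes were detected under the WT label, 12791 ± 509 (SD, n = 2), than under the Ythdf3-/- label, 11566 ± 397 (SD, n = 3), with every library of one label above every library of the other. The same order held after thinning to 6357862 counts, with 12166 ± 158 and 11419 ± 282 genes. This is the smallest p that 10 arrangements allow (exact permutation test, two-sided, p = 0.2). Ribosomal protein messages took 10.3 ± 2.59% and 7.71 ± 0.49% of counts, also p = 0.2 by the exact permutation test. The difference was -2.57 percentage points and became -0.743 without the library labelled WT 2. Mitochondrially encoded proteins took 0.755 ± 0.278% and 0.688 ± 0.104%, and the 10 most abundant genes of each library took 8.67 ± 3.45% and 7.51 ± 0.928% (exact permutation p = 0.8 for both).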

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

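The fit without the libraries labelled WT 2 and Ythdf3-/- 1 was chosen after seeing the data, and where a lone library stands for a label it is assumed to vary like the other group. Genes called numbered 0 and rose to 21 with no filter, 594 with DESeq2 and 0 to 1 with each library left out (1 without the library labelled WT 1); they stayed at 0 in the other settings, at 0.1 and at 2-fold. Genes at an unadjusted p under 0.05 numbered 541 and became 838 with no filter, 1759 with DESeq2, 285 with the replicate block and 488 to 1016 with each library left out. Lists called numbered 4 and became 0 with an estimated correlation, 1 with the replicate block (mitosis), and 1 to 8 with each library left out (8 without WT 1, 1 without WT 2, 2 without Ythdf3-/- 3). Libraries of equal number did not deviate together (r = -0.0043 and 0.00939 across genes). With 2 libraries labelled WT and so wide a spread between libraries, this cannot exclude a pairing by number. The fit with the block called 0 genes, as the main fit did. Ythdf3 stayed higher under the Ythdf3-/- label, by log2 fold changes of 3.0 to 4.6 with each library left out. Of 72 other named genes, 27 passed with DESeq2 and 10 with no filter, and 11 turned direction in 22 of 1060 gene and setting pairs; the cause was not tested. Without WT 2 and Ythdf3-/- 1 the turned log2 fold changes were -0.081 for Ier2, 0.0021 for ND4, 0.27 for ND6, 1.05 for Car1, -2.24 for Vpreb1, -0.54 for Emcn, -0.22 for Ddx3y and 0.23 for Malat1. Voom turned Emcn (-0.093) and Malat1 (0.013), and the replicate block turned Pecam1 (-1.53). Leaving out each library gave ranges of -0.49 to 1.52 for Ythdf1, -1.45 to 0.11 for ND4, -3.37 to 0.55 for ND6, -7.42 to 1.30 for Car1, -0.46 to 5.43 for Csf3r, -1.48 to 5.51 for Vpreb1, -0.40 to 0.48 for Emcn, -3.28 to 7.0 for Pecam1 and -0.74 to 0.22 for Malat1. The difference in the share of mitochondrially encoded proteins was -0.0667 percentage points, with a range of -0.263 to 0.13 leaving out each library and 0.126 without WT 2 and Ythdf3-/- 1; that of the 10 most abundant genes was -1.16, with -3.60 to 1.28 and 0.746.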

Other observations

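All tests of explanations below were chosen after the results they bear on were seen, as were the genes named here.

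Genes of long-term stem cells differed in how evenly they were read. Mllt3, a regulator of stem cell maintenance, ran from 332 to 536 CPM over the libraries. Hlf ran from 276.0 to 368 CPM and Meis1 from 239 to 593 CPM. Others were nearly missing in some libraries: Slamf1, which encodes the sorted marker CD150, was at 0.112 CPM in the library labelled WT 2 and between 28.9 and 51.6 CPM elsewhere. Fgd5 was at 0.315 and 0.713 CPM in the libraries labelled Ythdf3-/- 1 and 3 and between 33.8 and 78.6 CPM elsewhere, and Tek ran from 0.285 to 152 CPM. Cd34, whose protein the sort selected against, was at 2.2 CPM in the library labelled Ythdf3-/- 2 and between 58.2 and 244 CPM in the other 4. The Y-linked gene Eif2s3y was read in all 5 libraries, from 25.01 to 169 CPM. Xist, whose span overlaps that of Tsix, had 148 counts in the library labelled Ythdf3-/- 2 and at most 15 elsewhere. The sex of the mice was not worked out from these genes.

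Antigen presentation and lymphoid genes separated the libraries in ways that did not follow the labels. The MHC class II genes Cd74, H2-Aa, H2-Ab1 and H2-Eb1 made up 0.0082% of counts in the library labelled WT 2 (95% interval 0.00762 to 0.00881). They made up 0.274% (0.272 to 0.277) in the library labelled WT 1 and 0.103%, 0.134% and 0.116% in those labelled Ythdf3-/- 1, 2 and 3. Early B cell genes were read in the libraries labelled WT 1 and Ythdf3-/- 1. Cd79a stood at 228 and 264 CPM there and at 3.20 CPM or less in the other 3. Ly6d stood at 60.4 and 168 CPM against 0.441 CPM or less, and Vpreb3 at 42.5 and 304 CPM against 2.01 CPM or less. Blnk, at 52.6 and 178 CPM, was also present at 36.2 CPM in the library labelled Ythdf3-/- 3.

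DESeq2 called 594 genes between the labels and 638 in the highest of the other splits of the 5 libraries, with 4 of the 10 splits, the real one included, giving as many. For genes at an unadjusted p under 0.05 in edgeR the real split gave 541 and the highest other split 530, so 1 of the 10 splits gave as many. With 10 splits no share under 0.05 can be reached.

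Ythdf3 was high in the libraries labelled Ythdf3-/- 2 and 3 and low in the other 3. An exchange of the group labels would give the 2 knockout and 3 wild-type samples that the series text counts, where the labels give 3 and 2. It would need the library labelled Ythdf3-/- 1, with 2 counts, to be low by chance of capture, as 11.6% of 1726 genes at 20 to 80 CPM in the libraries labelled Ythdf3-/- 2 and 3 were. Correct labels may also hold, with an allele that leaves counted reads and both libraries labelled WT low by chance of capture, as 3.36% of those genes were; the library labelled Ythdf3-/- 1 would then also be low by chance, and 1.33% of the genes were as low in all 3. Those genes were picked as present in 2 libraries, so the shares are not test levels. Neither they nor the series text decide between these 2 explanations. Other mix-ups, such as an exchange of single libraries, were not tested and stay open.

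Many genes were abundant in some libraries and nearly missing in others. Few captured molecules per gene are a candidate explanation, since the share of values below 3% of a gene's highest CPM was 58.8% among genes of 100 to 300 counts and 0.418% among genes of 10000 counts or more. Those totals come from the same libraries, so being off in a library itself lowers a gene's total. The fall alone therefore does not establish capture as the cause. Unequal read depth was argued against as the source of the pattern as a whole. Thinning to the smallest total left that share at 40.7% against 40.9% among genes of 300 to 1000 counts. Before thinning it was 36.0% in the deepest library, labelled WT 1, and 46.1% in the shallowest, labelled Ythdf3-/- 1. Thinning leaves the shallowest library as it was, so a depth too low in all libraries was not tested. Genotype was argued against as the cause of the pattern as a whole, since 190 genes were fully on or off between the labels (10 times apart) and 177 to 228 between the other splits. Which of those 190 genes might still follow genotype was not tested.

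Red cell and erythroid progenitor RNA stood high in 1 library of each label, although a sort of lineage-negative cells positive for c-kit, Sca-1 and CD150 should remove both kinds of cell. All 14 transcripts of mature red cells examined were highest in the library labelled Ythdf3-/- 1, and 10 were at 3 times the next library or more, short of the 11 set for red cells or their RNA as the source. The other 4, Fech, Slc25a37, Bnip3l and Ube2l6, were also read in other libraries, which leaves that source open. For genotype, 0 of the other libraries labelled Ythdf3-/- held more globin than both labelled WT. That outcome rested on the library labelled WT 2, at 423.1 CPM of the 4 globin genes. Those other libraries (124.7 and 68.84 CPM) both lay above that labelled WT 1 (31.05 CPM). The test therefore cannot decide on genotype, though they did not share the high globin level. In the library labelled WT 2, 8 of 11 progenitor transcripts were highest. That is the number set, after the values were seen, for erythroid progenitors as a candidate source. Klf1 (169 CPM) and Ermap (143 CPM) stood well above the next library, while Epor and Blvrb were at 1.07 and 1.4 times it. Rhag and Hemgn were highest in the library labelled Ythdf3-/- 1 (26.3 and 78.5 CPM), and Car2 in that labelled WT 1. For the library labelled WT 2, genotype was argued against. Of the 11, 1 (Gata1) was higher in both libraries labelled WT than in all those labelled Ythdf3-/-. All 11 progenitor and 6 of the 14 red cell transcripts belong to the erythroid list.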
